A study of Mus musculus with 12 samples.

How the data were processed

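Liver RNA of 12 female mice aged 3 weeks was profiled, 6 KO and 6 WT, grouped by the genotype given in the labels. Livers were taken around 10 am and frozen, and libraries were made with the TruSeq Standard Total RNA kit, per the labels' protocols. The submitters' processing notes name FastQC, STAR, featureCounts, DESeq2 and the build mm10, with no version or order. The annotation, the strand setting and any filters are not given in the sources used here.

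The deposited signal is a table of normalized counts per gene, reads divided by one factor per library by the authors. Within each library all values were whole multiples of its smallest value above 0, to a tolerance of 0.001 reads, for 100% of values, so whole reads were recovered. Size factors computed from these reads with DESeq2 equalled the deposited scaling. The authors' deposited comparison gives a log2 fold change with its error, a p-value and an adjusted p-value per gene. DESeq2 on the recovered reads gave p-values within 2.05e-06 of the deposited ones. The deposited log2 fold changes had a median size of 0.447 of those from this run, so they are shrunken by a step not named in the headers. The shrinking was uneven. Deposited values were close to 0 for some of the largest falls, such as −0.096 for Scd1, −0.048 for Thrsp and −0.050 for Ces3b. They were −3.88 for Hamp2 and 1.64 for Igfbp2. The fold changes of genes given below are those computed here. The authors' deposited table has 1323 genes with an adjusted p under 0.05, 597 higher and 726 lower in KO, and all 601 genes called here are among them in the same direction.

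Before the data were examined, the test, the alternatives and 45 gene lists were fixed. limma 3.58.1 in R 4.3.3 was fitted to log2(normalized count + 1) with a mean-variance trend, genotype as the only term, and genes with a mean of at least 10 over the 12 libraries. P-values were two-sided and adjusted by Benjamini and Hochberg, with a threshold of 0.05. Gene lists with at least 5 tested members, 40 in all, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Alternatives were pseudocounts of 0.5 and 10, no filter and a minimum of 50, equal totals, equal upper quartiles, robust moderation, library quality weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, runs of neighbouring animal numbers as a block, where a gap of 10 starts a run, and leaving out each library. Added after seeing the data were the omission of WT 6 and KO 2 together, identical gene rows counted once, and an exact permutation test of each list's mean score over all splits into 6 and 6, two-sided and adjusted over the 40 lists. The score is the mean over members of the log2 difference from the WT mean. Of the gene rows, 508 equal an earlier row, 18 of them tested, such as Hba-a1 and Hba-a2; such copies cannot be told apart.

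The genes named are those of the targeted locus list, the 12 largest rises and falls among genes past the threshold with a mean of at least 50, leaving out symbols that start with Gm or end in Rik and pseudogenes marked by ps, and up to 4 genes with the smallest p per list. Others are said to have been chosen after their values were seen or are given as values of single libraries: Hr, Saa1, Adipoq, Cfd and Reg1 among these. Positions are from GENCODE M21 on GRCm38, and that of Gm3414 from RefSeq on GRCm38.p6. The genes Lcor and Fam184b fell under the filter, and mitochondrial and Y-linked genes were not analysed here.

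The procedure was tested on simulated counts for 13569 genes drawn with the dispersion of the WT livers, with 200 genes changed between KO and WT. limma recovered 49.3% of genes changed by 1.5-fold, 79.1% by 2-fold and 92.4% by 4-fold, all with the right sign, and 4.55% of its calls were false. DESeq2 had 9.09% false calls and edgeR 4.43%. In these data 0 of 40 lists were called by camera; simulated genes vary independently, so this says nothing about correlated lists. Depth per library is 21769795 to 31296485 reads. Intervals and floors cover counting error only.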

Results

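RNA sequencing was used to ask which liver transcripts differ between mice that lack Lcorl throughout the body and wild-type mice. Lcorl encodes a nuclear protein related to the ligand dependent corepressor Lcor. Total RNA was sequenced from the livers of 12 female mice at 3 weeks of age, the time of weaning, 6 of them Lcorl knockout (KO) and 6 wild type (WT). Each library came from a mouse with its own animal number. Expression was given as normalized read counts for 17714 genes. Whole reads could be recovered from these values, and the depth was 21769795 to 28655120 reads in WT and 27692285 to 31296485 in KO. Xist, the RNA of the inactive X chromosome, lay between 10323 and 15966 normalized counts in the 12 libraries. Genotype was compared with limma on log2(normalized count + 1) over the 13569 genes with a mean of at least 10. Fold changes are KO over WT on that scale, which understates the change of genes with low counts.

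The targeted transcript was almost absent from the KO livers. Lcorl, on chromosome 5 from 45697181 to 45857615 on the minus strand of GRCm38, measured 275 ± 26.5 normalized counts in WT and 0.471 ± 1.15 in KO (SD, n = 6 each; log2 fold change −7.78, SE 0.316, adjusted p = 1.36e-08, limma). In reads, the 6 WT libraries held 1594 and the 6 KO libraries 3, and all 3 came from KO 5. The pooled KO level was 0.171% of WT, with an exact binomial interval of 0.0352 to 0.5004% at 95% confidence that covers counting error only. Gm3414, a long noncoding RNA annotated inside Lcorl from 45719667 to 45727578, overlaps 2 annotated exons of Lcorl, so the 2 genes can share reads. It was singled out after its values were seen, held 285 reads in WT and 0 in KO, and was at least 105-fold lower, taking 3 reads over the group as the floor. Ncapg, which encodes a condensin subunit, lies from 45669919 to 45700546 on the opposite strand and shares 3366 bases with the end of Lcorl. Its level was 133 ± 47.6 normalized counts in WT and 50.5 ± 28.7 in KO. The difference did not pass the threshold in limma (log2 fold change −1.56, SE 0.415, adjusted p = 0.0508) but did in the authors' deposited comparison (DESeq2 adjusted p = 0.00642). Med28, a Mediator subunit gene from 45520229 to 45529276, measured 485 ± 25.6 normalized counts in WT and 483 ± 21.1 in KO (adjusted p = 0.967). Lcor and Fam184b had mean values below 10 and were not tested. The strand setting of the counting is not given in the sources used here, so overlapping genes are uncertain.

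**Figure D1:**
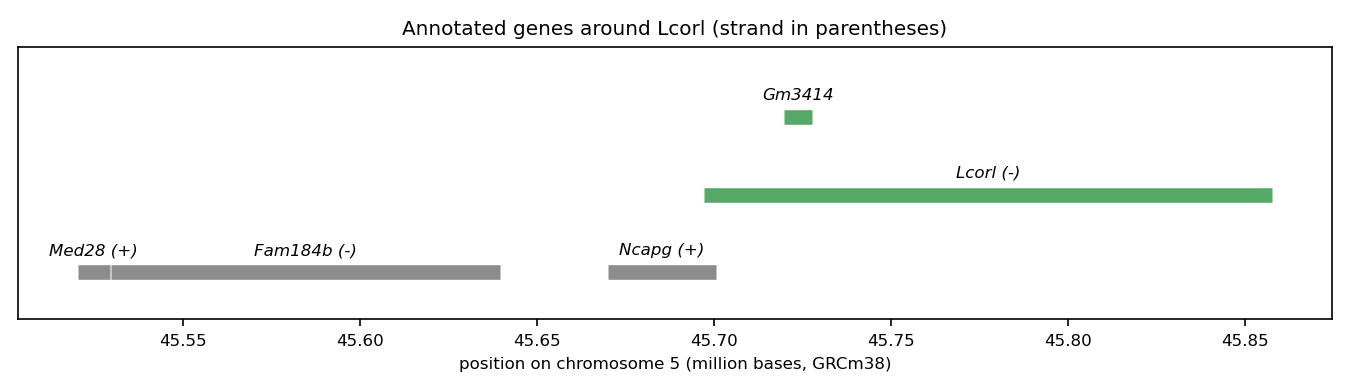
Positions of genes around Lcorl on chromosome 5 of GRCm38, in megabases, each bar running from a gene's annotated start to its end. Gm3414 lies within Lcorl, and Ncapg overlaps the end of Lcorl by 3366 bases.

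Beyond Lcorl, the KO livers had lower transcripts of fatty acid synthesis enzymes, of the hepcidin genes Hamp and Hamp2 and of the carboxylesterase genes Ces3a and Ces3b, and higher transcripts of insulin-like growth factor binding protein 2 and of alpha-fetoprotein. Among named genes with a mean of at least 50, the 12 largest rises ran from 3.38 for Igdcc4 (adjusted p = 0.00873), a gene of the immunoglobulin superfamily, to 1.70 for Igfbp2 on the log2 scale. Igfbp2, which binds insulin-like growth factors, rose 3.24-fold (8955 ± 2006 normalized counts in WT and 28627 ± 3792 in KO; adjusted p = 9.38e-05), and all 6 KO livers lay above all 6 WT livers. Trpm4, a cation channel gene, rose 3.36-fold (adjusted p = 9.95e-04) and Slc4a9, an anion transporter gene, 4.31-fold (adjusted p = 0.00475). Bex1 rose 4.44-fold, S100g, which encodes a calcium-binding protein, 6.73-fold, and Pde6c, a phosphodiesterase gene, 3.70-fold (adjusted p = 0.00442, 0.0350 and 0.0276). Amy2b rose 4.73-fold (adjusted p = 0.00344), but amylase genes are near copies among which reads can be divided, and GENCODE M21 lists it as a pseudogene. The microRNA host H19 and Mir675, which lies within H19, rose 3.46-fold and 3.41-fold (adjusted p = 0.0480 and 0.0482) and are not independent of each other. Among these genes the call was lost, with the adjusted p in parentheses, for S100g when any 1 library other than WT 6, KO 2, KO 5 or KO 6 was left out (up to 0.0845), Pde6c when any 1 library other than WT 6, KO 2, KO 3, KO 4 or KO 6 was left out (up to 0.0632), H19 when any 1 library other than KO 2 was left out (up to 0.0905) and Mir675 when any 1 library other than KO 2 was left out (up to 0.0922).

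Apart from Lcorl, the 11 largest falls lay between −6.32 for A1bg and −3.11 for Acacb on the log2 scale. The carboxylesterase genes Ces3b and Ces3a fell 61.4-fold and 24.6-fold (adjusted p = 0.00566 and 0.00688), but they are near copies that can share reads. Hamp2 and Hamp, the paralogous hepcidin genes, fell 15.5-fold and 18.9-fold (adjusted p = 0.00151 and 0.0234). The call was lost for Hamp without WT 1, WT 4 or WT 5 (up to 0.0549). Mup3, a major urinary protein gene of a large family of near copies, fell 18.7-fold (adjusted p = 0.00151). Ntrk2, a neurotrophin receptor gene, fell 15.3-fold, and Chrna4, an acetylcholine receptor subunit gene, 38.5-fold (adjusted p = 0.00181 and 0.00816). A1bg varied from 57.2 to 1860 normalized counts between WT livers and from 0 to 43.8 between KO livers (adjusted p = 0.00907).

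At an adjusted p under 0.05, 601 genes differed between KO and WT livers, of which 237 rose and 364 fell. With a fold of at least 1.5 as well, 362 genes differed, 121 higher and 241 lower. The KO and WT ranges did not overlap for 401 genes, or 2.96% of those tested, where chance gives 0.216%. The number of genes depended on single livers: it was 224 without KO 4, 237 without WT 3, 260 without KO 1, 269 without WT 5, 271 without WT 1, 304 without WT 2, 340 without WT 4, 909 without KO 6 and 932 without WT 6. With the fold threshold it was 168 without KO 4, 178 without WT 3, 179 without KO 1, 189 without WT 1, 193 without WT 5, 213 without WT 2, 229 without WT 4 and 567 without KO 6. Of the 76 named genes past the threshold, 47 stayed past it without each single library. With runs of neighbouring animal numbers as a block the numbers were 158 and 126, and DESeq2 on the recovered reads gave 1349 and 639. Genotype was uneven over the runs. WT 2 and WT 3 formed a run without KO livers, and KO 2, KO 3 and KO 4 shared a run with WT 4 alone. A call that ends with the block can reflect this smaller contrast and does not by itself show an effect of the run. The block ended the call of 41 of the 76 named genes, with adjusted p from 0.0569 to 0.196, and 35 kept it, among them Lcorl, Igfbp2, Afp, Scd1, Acacb, Me1, Hamp and Mup3. The calls that ended included those of Igdcc4, Thrsp, A1bg, Chrna4, S100g, H19, Mir675, Cyp2a4, Ugt2b1, Ebp, Cyp4a14, Acadm, Acadl, Fabp1, Pklr, Cyp2b10, Gstm3, Aldh1a1, Pgd, Asns, Cth, Rrm2, Aurka, Birc5, Ccna2, Il1rn, Bst2, Per1, Dusp1, Mttp, Lipg, Lpl, Pparg, Aldh1a7, Rdh16, Rbp4, Rdh11, Mfsd2a, Fetub and Lum. WT 6 held transcripts of fat tissue, with 53.4 normalized counts of Adipoq and 101 of Cfd, against at most 0.9755 and 2.07 in the other livers, and KO 2 alone held the pancreatic Reg1, at 126. With both of these livers left out, an alternative chosen after seeing the data, 913 genes differed and 468 with the fold threshold.

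**Figure D2:**
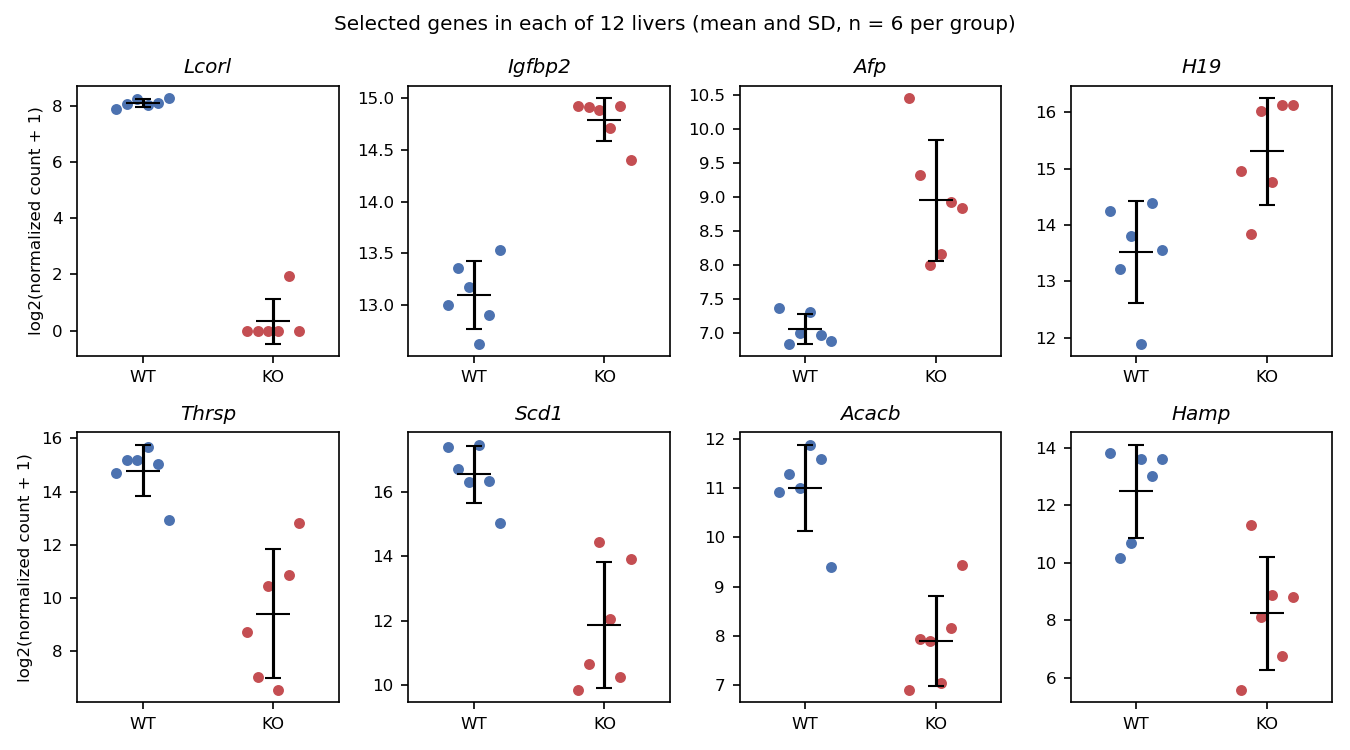
Expression of 8 genes in each liver on the log2(normalized count + 1) scale, with points for single livers, WT left and KO right, and bars for the mean and SD of 6 livers. The 6 KO livers lie above all WT livers for Igfbp2 and Afp and below them for Lcorl, Thrsp and Scd1, while the ranges overlap for H19, Acacb and Hamp.

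Transcripts of fatty acid synthesis were lower in KO livers. Of the 21 measured genes of this list, 13 fell, 0 rose and 8 did not pass the threshold, and 17 fell when adjusted over the list alone; the median log2 change was −1.42. Scd1, which encodes the stearoyl-CoA desaturase, fell 25.5-fold (109340 ± 57163 normalized counts in WT and 7614 ± 9023 in KO; log2 fold change −4.67, SE 0.764, adjusted p = 0.00573). Acacb and Acaca, which encode acetyl-CoA carboxylases, fell 8.66-fold and 2.67-fold (adjusted p = 0.00317 and 0.00442), and Me1, the malic enzyme, 4.601-fold (adjusted p = 0.00181). The list was lower by camera (adjusted p = 2.39e-12; adjusted p = 0.343 with an estimated correlation). An exact permutation test of the mean list score, chosen after seeing the data, gave p = 0.00433. Its adjusted p over 40 lists was 0.0433, and 5 of 6 KO livers lay below all WT livers. This adjusted value was reached only together with the other lists that passed. Among these, the thyroid hormone list shares Thrsp and Me1 with the fatty acid synthesis list. WT 6 had the lowest WT score, −0.93, below the −0.80 of KO 6.

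Genes that respond to thyroid hormone went both ways. Of 12 measured, 7 were lower and 5 higher in KO, and 5 fell and 7 did not pass; 5 fell and 1 rose when adjusted over the list alone. The 5 were Thrsp, which fell 42.1-fold (32653 ± 14935 normalized counts in WT and 1858 ± 2746 in KO; log2 fold change −5.40, adjusted p = 0.00743), Me1, Gpd2 (1.86-fold, adjusted p = 0.00384), the deiodinase gene Dio1 (1.93-fold, adjusted p = 0.0119) and Hr. Thrsp and Me1 are members of the fatty acid synthesis list too. The median log2 change was −0.24 (camera adjusted p = 0.0340, adjusted p = 0.751 with an estimated correlation, fry adjusted p = 0.0620). The exact permutation test gave p = 0.00216, which is the smallest it can give, and an adjusted p = 0.0433; 6 of 6 KO livers lay below all WT livers. That result rested on Thrsp and Me1. Of the other 10 genes, 5 were lower and 5 higher, and their score, chosen after seeing the data, differed by −0.02 (exact permutation p = 0.896). The camera call ended without WT 4 (adjusted p = 0.0538), KO 1 (0.0589) or KO 5 (0.0505).

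Genes of fetal and neonatal liver were higher in KO livers. Of 18 measured, 7 rose, 0 fell and 11 did not pass, and 10 rose when adjusted over the list alone; the median was 0.51. Afp, which encodes alpha-fetoprotein, rose 3.70-fold (134 ± 21.4 normalized counts in WT and 586 ± 422 in KO; log2 fold change 1.89, SE 0.329, adjusted p = 0.00801). Gpc3, a glypican gene, rose 2.54-fold, Tff3, a trefoil factor gene, 5.30-fold, and Grb10, an imprinted gene, 1.35-fold (adjusted p = 0.00654, 0.00531 and 0.00569). The list was higher by camera (adjusted p = 1.56e-06; adjusted p = 0.122 with an estimated correlation). The exact permutation test gave p = 0.00216 and an adjusted p = 0.0433, and 6 of 6 KO livers lay above all WT livers. Here too the adjusted value was reached only together with the other lists that passed, the thyroid hormone list among them.

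Cell cycle genes were lower on average, with a wide spread between KO livers. All 30 measured genes were lower in KO; 4 fell past the threshold over all genes, and 30 when adjusted over the list alone. The 4 were Rrm2, a ribonucleotide reductase subunit gene (3.39-fold lower), the mitotic kinase gene Aurka (3.05-fold), Birc5 (2.64-fold) and the cyclin gene Ccna2 (2.62-fold), with adjusted p between 0.0409 and 0.0432. These calls were lost for Rrm2 when any 1 library other than WT 6, KO 3 or KO 6 was left out (up to 0.0874), Aurka when any 1 library other than WT 6, KO 3 or KO 6 was left out (up to 0.0936), Birc5 when any 1 library other than WT 6, KO 3, KO 5 or KO 6 was left out (up to 0.0929) and Ccna2 when any 1 library other than WT 6, KO 3 or KO 6 was left out (up to 0.0929). The median was −1.26 (camera adjusted p = 1.25e-14; adjusted p = 0.709 with an estimated correlation). The exact permutation test gave p = 0.00649 and an adjusted p = 0.0519, which did not pass. The mean cell cycle score was −1.83 in KO 1, −2.37 in KO 2 and −1.30 in KO 4, and −0.30 in KO 3, −0.79 in KO 5 and −0.43 in KO 6, where WT livers lay between −0.65 and 0.63, so KO 3 and KO 6 were within the WT range. Of 25 measured genes of cholesterol synthesis, 1 fell, the sterol isomerase gene Ebp (1.59-fold, adjusted p = 0.0178), 24 did not pass, and 11 fell when adjusted over the list alone. The median was −1.10 (camera adjusted p = 4.33e-08; adjusted p = 0.829 with an estimated correlation; exact permutation p = 0.102). The mean list score was −2.39 in KO 1, −2.53 in KO 2, −0.17 in KO 3, −2.28 in KO 4, −0.04 in KO 5 and 0.25 in KO 6, while WT livers lay between −0.28 and 0.30; the 3 lowest KO livers were the same 3 as for the cell cycle score. Nsdhl, a sterol dehydrogenase gene, measured 3957 ± 588 normalized counts in WT and 1682 ± 1658 in KO (adjusted p = 0.0932).

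**Figure D3:**
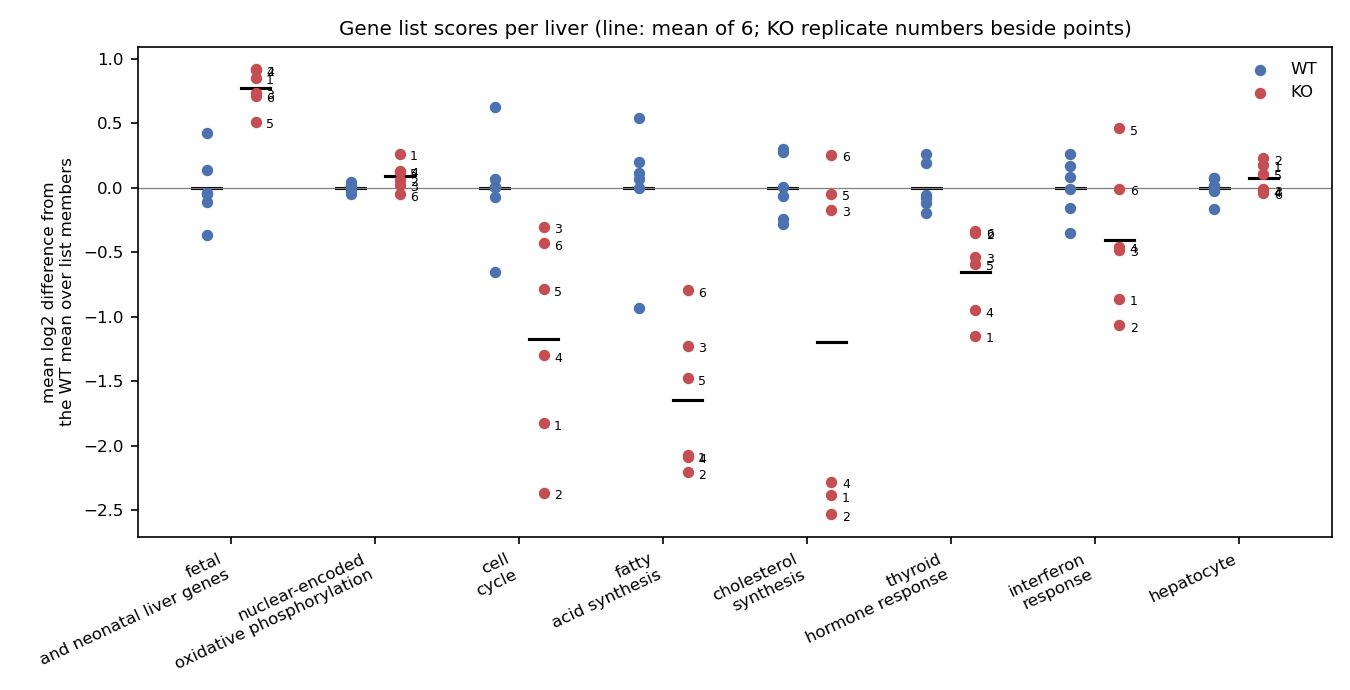
Mean log2 difference from the WT mean over the measured members of 8 gene lists, one point per liver, with KO replicate numbers beside the points and a line at each group mean. KO livers lie above WT for fetal and neonatal genes and are far apart for cholesterol synthesis, from −2.53 to 0.25.

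Camera called 6 further lists, and each had an estimated-correlation adjusted p of 0.829. Interferon response genes were lower on average, 18 of 24 lower and 6 higher, with 2 fallen, Ifi27 (1.86-fold, adjusted p = 0.00317) and Bst2 (1.73-fold, adjusted p = 0.0113), and 5 when adjusted over the list alone (camera adjusted p = 0.00154). Glucose handling genes were lower, with 3 of 21 fallen: Pygl, the liver glycogen phosphorylase (1.90-fold), Khk, ketohexokinase (1.91-fold), and Pklr, pyruvate kinase (4.30-fold), with adjusted p = 0.00181, 0.00327 and 0.0184; adjusted over the list alone, 6 fell and 1 rose (camera adjusted p = 0.0268). Stellate cell and fibroblast genes were lower, with 1 of 18 fallen, the proteoglycan gene Lum (1.65-fold, adjusted p = 0.0440), and 2 when adjusted over the list alone (camera adjusted p = 0.0226). Heat shock, erythroid and nuclear-encoded oxidative phosphorylation genes held 0 of 12, 0 of 15 and 0 of 25 past the threshold in limma and 0 when adjusted over the list alone, with medians of −0.25, −0.73 and 0.10 (camera adjusted p = 0.0371, 0.0270 and 0.00217). In those 3 lists together, 11 of 52 genes had an unadjusted p under 0.05, against 3177 of all 13569 tested genes. In the same lists edgeR called 0 and DESeq2 2. The call of Lum was lost when any 1 library other than WT 4, KO 3 or KO 6 was left out (up to 0.0969). Camera calls were lost for glucose handling without WT 4 (0.0566) or KO 3 (0.0694), for stellate cells without WT 3 (0.0506) or KO 1 (0.204), and for oxidative phosphorylation without KO 1 (0.0543). They were also lost for heat shock without WT 3 (0.1701), WT 4 (0.0932), KO 1 (0.0743), KO 5 (0.0505) or KO 6 (0.103), and for erythroid genes without WT 2 (0.0828), WT 5 (0.0767), KO 1 (0.0743), KO 2 (0.0548) or KO 5 (0.0544). With the block, the calls of stellate cells (0.0602) and erythroid genes (0.464) ended. The interferon score was 0.46 in KO 5, above every WT liver (highest 0.26), and −0.01 in KO 6, within the WT range, while the other 4 KO livers lay below every WT liver. KO livers below every WT liver numbered 3 for glucose handling, 3 for stellate cells, 1 for heat shock and 1 for erythroid genes. For oxidative phosphorylation 4 lay above every WT liver and KO 6 below. Exact permutation tests of these 6 mean scores gave p from 0.0260 to 0.139, none below 0.05 after adjustment. Camera with the preset correlation called at least 11 lists in 68 of 100 splits of the 12 livers, so its count of 11 does not set the genotypes apart from other groupings.

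In the growth hormone and insulin-like growth factor list, Igfbp2 alone of 18 genes passed in limma, and 1 rose and 2 fell when adjusted over the list alone. In the authors' deposited comparison Igf1 passed too (DESeq2 adjusted p = 0.0221), while Igfals (0.0504) and Igfbp1 (0.106) did not. Igf1 measured 17363 ± 7540 normalized counts in WT and 7026 ± 3764 in KO (log2 fold change −1.34, adjusted p = 0.0746), Igfals, which encodes the acid-labile subunit, had a log2 fold change of −1.93 (adjusted p = 0.0768) and Igfbp1 one of 2.32 (adjusted p = 0.138). Of 18 female-biased liver genes, Cyp2a4 fell 6.25-fold (adjusted p = 0.00554) and A1bg fell as above. Of 14 male-biased genes, Nudt7 (2.52-fold) and Ugt2b1 (1.65-fold) fell, and Susd4 (2.45-fold) and Cyp2d9 (2.02-fold) rose (adjusted p = 9.95e-04, 0.0234, 0.00315 and 0.00317). Adjusted over the list alone, 3 rose and 4 fell among female-biased genes, and 2 rose and 5 fell among male-biased genes. The call was lost for Ugt2b1 without WT 1, WT 3, WT 5 or KO 4 (up to 0.0593). Camera adjusted p was 0.116 and 0.0542 for these 2 lists and 0.991 for the growth hormone list. Camera tests a shift in a common direction, and in the growth hormone list 10 genes were lower and 8 higher. The 0.991 therefore does not show an absence of change in that list. The female-biased list passed, as lower in KO, without WT 4 (0.0310) or KO 6 (0.0347). The male-biased list passed, also as lower, without WT 4 (0.0158), KO 3 (0.0382) or KO 6 (0.0347).

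Among metabolic lists without a camera call, fatty acid oxidation, lipoproteins, retinoids and acute phase genes held calls in both directions. In fatty acid oxidation, Cyp4a14 (2.68-fold), Acadm (1.47-fold) and Acadl (1.25-fold) rose and the fatty acid binding protein gene Fabp1 fell 2.25-fold, out of 31 (adjusted p = 0.0203, 0.0212, 0.0465 and 0.0216). Among 23 lipoprotein genes 2 rose and 3 fell, the latter Apoc3 (1.63-fold), Mttp (1.35-fold) and the endothelial lipase gene Lipg (5.08-fold), with adjusted p = 0.00224, 0.00607 and 0.0183. Lpl and Pparg rose 1.63-fold and 1.82-fold in the lipid uptake list of 17 (adjusted p = 0.0184 and 0.0244). The bile salt export pump gene Abcb11 fell 1.48-fold (1 of 19 bile acid genes, adjusted p = 0.00688). In the xenobiotic list 3 of 23 fell, with Cyp2b10 6.98-fold lower (adjusted p = 0.00953); the calls of the other 2 were lost for Gstm3 when any 1 library other than WT 6 or KO 6 was left out (up to 0.0895) and Aldh1a1 when any 1 library other than KO 2, KO 5 or KO 6 was left out (up to 0.1004). In the retinoid list Aldh1a7 and Rdh11 fell and Rdh16 and Rbp4 rose, of 14, and each of these calls was lost in some omissions: Aldh1a7 when any 1 library other than WT 6, KO 2, KO 3, KO 5 or KO 6 was left out (up to 0.0686), Rdh11 when any 1 library other than WT 6, KO 5 or KO 6 was left out (up to 0.104), Rdh16 when any 1 library other than WT 4, WT 6, KO 2, KO 3 or KO 6 was left out (up to 0.0978) and Rbp4 when any 1 library other than WT 6, KO 3 or KO 6 was left out (up to 0.0971). In the periportal list, Cyp2f2 (2.92-fold), Pigr (1.96-fold) and Mfsd2a (6.73-fold) fell of 16 (adjusted p = 0.00151, 0.0119 and 0.0147). That list missed camera's threshold (adjusted p = 0.0622) but passed it without WT 1 (0.0463), WT 6 (0.0384), KO 1 (0.0364) or KO 4 (0.0149). It passed the exact permutation test of its mean score (adjusted p = 0.0433, and adjusted p = 0.829 in camera with an estimated correlation). That 0.0433 was reached only together with the other lists that passed. Among the periportal genes 9 were lower and 7 higher, with a median log2 change of −0.12 and a mean of −0.34. A few large falls therefore weigh on the mean score, and most of the list did not shift by that much. In limma, 0 of 16 pericentral genes passed (6 at an unadjusted p under 0.05, 0 in edgeR, 3 in DESeq2). Of 13 NRF2 targets Taldo1 and Pgd fell, of 20 ATF4 targets Asns and Cth rose, of 14 glucocorticoid genes and 17 clock genes Per1 rose, of 14 immediate early genes Dusp1 fell, and of 23 acute phase genes Il1rn rose and Hamp fell. Camera called immediate early genes without WT 5 (0.0480), KO 4 (0.0397) or KO 6 (0.0444). It called acute phase genes without KO 5 (0.0166) or KO 6 (0.0444). With no library left out, camera's direction was higher in KO for both lists. Of the immediate early genes 11 were then higher and 3 lower, with a median log2 change of 0.44. Of the acute phase genes 17 were higher and 6 lower, with a median of 0.32. Adjusted over the list alone, the counts were 6 higher and 3 lower for fatty acid oxidation, 4 and 4 for lipoproteins, 5 and 0 for lipid uptake, 0 and 1 for bile acids, 3 and 6 for the xenobiotic list, 3 and 4 for retinoids, 0 and 4 for periportal genes, 0 and 2 for NRF2 targets, 3 and 0 for ATF4 targets, 2 and 1 for acute phase genes, 1 and 0 for glucocorticoid and for clock genes, and 0 and 1 for immediate early genes. The calls were lost for Acadl when any 1 library other than WT 6, KO 2, KO 3 or KO 6 was left out (up to 0.0983), Acadm without WT 1, WT 3 or KO 4 (up to 0.0561), Cyp4a14 without WT 3 or WT 5 (up to 0.0529), Fabp1 without WT 3, WT 5, KO 1 or KO 4 (up to 0.0563), Lipg without KO 4 (0.0503), Pparg without WT 1, WT 2, WT 3, WT 5, KO 1 or KO 4 (up to 0.0594) and Pgd without WT 1, WT 2, WT 3, WT 5, KO 1 or KO 4 (up to 0.0580). They were also lost for Cth when any 1 library other than WT 2, WT 6, KO 3 or KO 6 was left out (up to 0.0923), Per1 when any 1 library other than WT 4, WT 6, KO 1 or KO 6 was left out (up to 0.0807), Dusp1 when any 1 library other than WT 6 or KO 5 was left out (up to 0.106), Il1rn when any 1 library other than WT 6, KO 3 or KO 6 was left out (up to 0.0867) and Hamp without WT 1, WT 4 or WT 5 (up to 0.0549). The median was above 0 and the mean below 0 for the xenobiotic, lipoprotein, bile acid and Polycomb target lists, and camera's direction differed from the median for the bile acid, Polycomb target and cholangiocyte lists.

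Markers of liver cell types and of other cells were mostly within the spread. Of 16 hepatocyte genes, Fetub rose 1.42-fold (adjusted p = 0.0138), and of 11 cholangiocyte genes Pkhd1 fell 1.73-fold (adjusted p = 0.00181). Adjusted over the list alone, 1 hepatocyte gene rose, and 1 cholangiocyte gene rose and 1 fell. In limma, 0 of 16 macrophage, 0 of 20 endothelial, 0 of 15 T and NK cell, 0 of 7 B and plasma cell and 0 of 12 neutrophil genes passed, nor any of 14 PRC2 components, 14 Polycomb target genes, 17 endoplasmic reticulum chaperones, 25 urea cycle and amino acid genes and 5 nuclear long noncoding RNAs. The smallest adjusted p in these lists was 0.0795, for Gpt2, an alanine aminotransferase gene. With the pericentral genes, these 11 lists hold 161 genes. Of these, 25 had an unadjusted p under 0.05, a smaller share than the 3177 of all 13569 tested genes. In these 11 lists edgeR called 0 and DESeq2 7. The 29 lists without a camera call had adjusted p from 0.0542 to 0.991. Leaving out a library brought a camera call, as lower in KO, for endoplasmic reticulum chaperones without KO 2 (4.64e-04). Endothelium was likewise called lower without WT 6 (0.00808) or KO 6 (0.0237), and urea cycle genes were called higher without KO 6 (0.0169). The block of animal-number runs brought calls for chaperones (0.0173), lower in KO, and for macrophages (0.0173) and T and NK cells (0.00826), both higher. Serum amyloid A1 reached 72515 normalized counts in KO 2, against 306 to 12702 in the other libraries, and the acute phase score was 2.05 in KO 2 and −1.04 to 0.55 in the other libraries. The 5 lists for the targeted locus, mitochondrial genes, pancreas, adipocytes and sex chromosomes had too few measured members and were not tested. Of the 44 genes of the Polycomb target list, 34 had values and 14 passed the filter on low values, so most were not tested.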

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

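The tests of the cell cycle and cholesterol patterns were chosen after the results were seen, while those of Ncapg and of other groupings of the livers were set out earlier. A single liver was singled out where its gap to the nearest of the other 5 exceeded the critical value of Dixon's test as a share of the range of its group. Of 352 checks on 176 genes, 25 met this, where chance gives 17.6, and 11 of the 25 were in WT 6, 4 in KO 2 and 3 in WT 1.

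In WT 6, normalized counts were lowest of the WT livers for Thrsp at 7730 (the others 26616 to 52883), Ebp at 5194 (6746 to 7710), Pklr at 9570 (15868 to 20298), Lpin1 at 3149 (16205 to 21771), Lipg at 629 (1208 to 1556), Rdh11 at 808 (1559 to 1906) and Dnase1l3 at 1231 (1928 to 2484). They were highest for Acadl at 7759 (6257 to 6741), Osgin1 at 7618 (1630 to 2350), Hoxb3 at 43.8 (30.2 to 33.1) and Meg3 at 444 (105 to 173). In WT 1, normalized counts were lowest for Il1rn at 47.0 (77.1 to 91.7), Tef at 3167 (5589 to 7609) and E130012A19Rik at 76.4 (113 to 126). Igfbp1 was lowest in WT 3 at 199.98 (2738 to 12600), and Ifi27 highest in WT 4 at 2040 (1425 to 1585).

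In KO 2, normalized counts were lowest of the KO livers for Aldh1a1 at 1268 (3480 to 5512) and Aldh1a7 at 393 (1121 to 2006), and highest for Dnajc3 at 10776 (4711 to 6344) and E130012A19Rik at 249 (123 to 140). In KO 5 they were highest for Lcorl at 2.83, where the other KO livers held 0, and Tsc22d3 at 8457 (3898 to 4624). In KO 4 they were highest for Mmp8 at 57.8 (7.31 to 16.2) and Retnlg at 82.8 (16.4 to 25.5), both neutrophil markers, and in KO 6 for Egfl7 at 1357 (1031 to 1132).

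Cell cycle genes were lower in KO livers, with a median log2 change of −1.26 over 30 genes, and 2 changes of cell content were weighed. An equal loss of all other liver cell types would lower 99 of their markers by a like amount. The cell cycle score minus the score of these markers differed by −1.13 between KO and WT (exact permutation p = 0.0108). This argues against such an equal loss as the whole cause. Scores of single types went both ways in KO against WT: −0.28 for stellate cells, −0.20 for endothelium and −0.03 for B and plasma cells. They were 0.15 for T and NK cells, 0.12 for macrophages, 0.06 for cholangiocytes and 0.05 for neutrophils. Such shifts cancel in the pooled score, so a loss of any single type was not tested and stays open. For fewer erythroid precursors the same difference was −0.8547 over 9 erythroid genes other than haemoglobins (exact permutation p = 0.0433), but −0.60 over all 15 (p = 0.167), −0.70 over 12 with 3 identical copies among the haemoglobins counted once (p = 0.113) and −0.23 over the 6 haemoglobins (p = 0.658). The scores themselves differed by −0.31 over the 9 (exact permutation p = 0.307) and −0.56 over the 15 (p = 0.136), so a loss of erythroid precursors stays open. Genotype stays open as a hypothesis, as does a smaller share of dividing cells of any type, and the exact permutation test of the score itself missed the threshold after adjustment over 40 lists (adjusted p = 0.0519); KO 3 and KO 6 lay within the WT range.

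Cholesterol synthesis genes were far apart between KO livers, with scores of −2.39, −2.53 and −2.28 in KO 1, KO 2 and KO 4 and of −0.17, −0.04 and 0.25 in KO 3, KO 5 and KO 6. With equal library totals the range of the score over the KO livers was 2.925. Under the main scaling it was 2.786 over the KO livers and 0.583 over the WT livers. Equal totals changed no library by more than 0.111 on the log2 scale, so scaling between libraries did not account for the range over KO livers. The 3 KO livers of one run of animal numbers still ranged over 2.361, which argues against the run. The hepatocyte score ranged over 0.2649 only, which argues against different shares of hepatocytes. No biological explanation was tested for this split, since the labels give no group that follows it.

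Ncapg was lower in KO, by −1.56 on the log2 scale, and did not pass the threshold in limma (adjusted p = 0.0508). It did pass in the authors' deposited comparison (DESeq2 adjusted p = 0.00642), so its call depends on the tool. Reads from the overlapping end of Lcorl were weighed against a share in the change of cell cycle genes, a list that does not hold Ncapg. With the cell cycle score as a covariate the genotype effect on Ncapg was −0.1635 (95% interval −0.64 to 0.31), and since the interval excludes −1.56, it argues against shared reads as the whole cause. A shared change with the cell cycle genes may account for most of it. The KO livers held 329 reads of Ncapg but 3 of Lcorl, so at most 3 Ncapg reads were counted for Lcorl as well. That argues against reads being counted for both genes. Lcorl reads counted for Ncapg alone were not tested, so a part of up to 0.64 from them stays open.

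The 601 genes past the threshold were more than in any of the other splits tried: of 100 splits of the 12 livers into 6 and 6, 1, the real one, gave as many, and the highest other gave 30. With a fold of at least 1.5, 1 of 100 gave 362 or more, and the highest other gave 19. Counting genes of the fixed lists adjusted over the list alone, 1 of 100 gave 162 or more, and the highest other gave 53. For camera with the preset correlation, 68 of 100 splits gave 11 lists or more and the highest other gave 20, so chance cannot be excluded for the number of lists.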

How the results depend on the processing

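Chosen after the data were seen were the exact permutation test of list scores, the thyroid score without shared genes, the omission of WT 6 and KO 2, and the counting of identical genes once. For Lcorl, KO against WT, the direction was kept and the value passed the threshold under every setting run, with log2 fold changes from −9.18 with DESeq2 to −4.77 with a pseudocount of 10. The number of genes, 601 as reported, was 1349 with DESeq2, 158 with runs of animal numbers as a block, 913 without WT 6 and KO 2, and 224 to 932 without single libraries. With a fold of at least 1.5, 362 became 639 with DESeq2, 126 with the block and 168 to 567 without single libraries. The genes of each fixed list adjusted over the list alone, 162 in all, became 92 with the block and 121 to 210 without single libraries. The number of lists called, 11 with camera, was 0 with an estimated correlation, 2 with fry, 4 with the exact permutation test and 7 to 16 without single libraries. Of the 4, the periportal genes were not among the 11. The 4 share an adjusted p of 0.0433 in the exact permutation test, which each reached only together with the others. The thyroid hormone list among them rested on Thrsp and Me1, members of the fatty acid synthesis list too, so the 4 are not independent. The block costs degrees of freedom, and WT 2 and WT 3, with no KO liver in their run, add nothing to its contrast. Livers were left out one by one, so fewer samples enter. Other causes were not tested. Pseudocounts, filters, scaling, robust moderation, quality weights and edgeR kept the number of genes between 536 and 861. DESeq2 shared all 601 genes, edgeR 528 and the block 143. Of the values of named genes under the alternatives, 3975 kept their side of the threshold and direction, 292 lost and 91 gained the call, and 0 turned. The 3975 also hold genes outside the threshold that stayed outside, and only genes past it could lose a call. Depth was 21769795 to 31296485 reads, and in simulated data of this size limma recovered 49.3% of genes changed by 1.5-fold, so smaller changes can be missed. Both simulated groups had the dispersion of the WT livers, while 58.9% of tested genes had a larger variance in KO, so recovery in these data may be lower.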

Other observations

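All tests in this part were chosen after the data had been seen, except that of the genes near Lcorl. Among gene families taken by the start of their symbols, 151 were tested with camera, and collagens, carboxylesterases and gamma-protocadherins were lower in KO (adjusted p = 0.00149, 0.00181 and 0.00181), as were the Ifi and Mcm families (0.0463 each); the adjusted p = 0.965 with an estimated correlation for each of the 5. Of 37 collagen genes 28 were lower and 4 fell, among them Col4a4, with 77.0 ± 25.1 normalized counts in WT and 23.5 ± 8.75 in KO, and Col4a3 (adjusted p = 0.00344 and 0.00793). Of 13 carboxylesterase genes 11 were lower and 4 fell. All 12 tested Pcdhga genes were lower and 0 passed in limma (12 at an unadjusted p under 0.05, 0 in edgeR and 0 in DESeq2); these genes share exons, so their reads are not independent.

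Among single genes picked after their values were seen, Mug2, a protease inhibitor gene, fell by 1.59 on the log2 scale (adjusted p = 9.38e-05) and Cela1 by 1.12 (adjusted p = 0.00533), while Cd63 rose by 1.13 (adjusted p = 3.53e-04) and the leptin receptor gene Lepr by 1.46 (adjusted p = 0.0253). Mettl7a3 measured 71.7 normalized counts in WT 1 and 91.3 in WT 2, and at most 0.963 in any other liver. Egr1 and Fos, which respond early to stimuli, measured 5459 and 423 in KO 5, and Fos 382 in WT 6. Sqle, a cholesterol synthesis gene, measured 154, 159 and 151 normalized counts in KO 1, KO 2 and KO 4, and 3282, 3691 and 6021 in KO 3, KO 5 and KO 6, with WT livers from 3779 to 5167.

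It was asked whether KO livers spread further than WT livers. The mean distance to the group mean was 0.356 in KO and 0.303 in WT, a difference of 0.05287 (exact permutation p = 0.121), and 58.9% of genes had a larger variance in KO, which leaves a difference in spread open.

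A chromosome segment inherited with the targeted allele could change genes near Lcorl. Within 10 megabases, 4 of 53 tested genes differed, 7.55% against 4.42% elsewhere (Fisher's exact test, two-sided, p = 0.2971; odds ratio 1.77, 95% interval 0.461 to 4.84). The test set out earlier took a p of 0.05 or more as evidence against such a segment, but that was too weak, since the interval holds 1 as well as larger values, and the question stays open. The 4 genes were Man2b2, Prom1, Qdpr and Pi4k2b, all lower in KO.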
